A study of Mus musculus with 14 samples.

How the data were processed

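Gene expression was measured on Affymetrix Mouse Gene 1.0 ST arrays, which carry 1 or more probe sets per transcript. The 14 samples were sorted cells from limbs of C57BL/6 mouse embryos at embryonic day 16.5. Per the labels' protocols, the limbs were digested with collagenase and dispase, red blood cells were lysed, and stained cells were separated by fluorescence-activated cell sorting. All sorted cells carried CD9, and the groups differed in CD73 and Thy1. OCP1 was CD73+ Thy1- (3 arrays), OCP2 was CD73- Thy1- (3 arrays), OCP3 was CD73- Thy1+ (4 arrays) and OCP4 was CD73+ Thy1+ (4 arrays). Biotin-labelled cRNA was made from total RNA, per the labels' protocols.

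The submitters' processing notes name RMA (background correction, quantile normalization and summary of probes into probe sets) and limma, with no version; versions and an annotation build are not given in the sources used here. The deposited value table holds 1 intensity per probe set and array on a linear scale, and log2 of each intensity was taken here. The planned test had assumed log2 values as deposited. Array medians lay between 328.1 and 346.8 intensity units. The authors' deposited comparison table holds log2 differences of OCP4 with each other group, a mean log2 level over all arrays, adjusted p-values and gene symbols. Its probe numbers were read as row positions of the value table, and this was checked on the values: the largest gap was 5.00e-08 log2 units over 35556 rows. All signed columns of that table run as OCP4 minus the other group, opposite to the wording of their headings.

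Of 35556 probe sets, 25254 had a symbol in the authors' deposited table and 10302 had none. A further check found 26 symbols that had been turned into calendar dates, and these were treated as unnamed. The remaining probe sets gave 21734 different symbols. Of these, 18706 were current symbols of the mouse reference gene table used for names, 2293 were found only among its synonyms and 735 were not matched and kept the file's name. The deposited table gives a single symbol per probe set, so probe sets that match several genes were not identified here. For the 1920 symbols with more than 1 probe set, the probe set with the highest mean over the arrays was used. Probe sets of a gene can differ: the dimmer sets of Prnd and Epyc showed log2 differences of 0.15 and 0.31 between OCP1 and OCP2 where the brighter ones showed -2.46 and 1.41, and that of Gdf5 0.47 against 1.16. No filter on dim probe sets was applied. The values of 701 rows were identical to those of another row. No column of per-sample values was left out, and neither batch nor scan day is given in the sources used here.

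Replicates were compared before averaging. Pearson correlations over genes were 0.9955 to 0.9979 for 18 pairs within groups and 0.9843 to 0.9945 for 73 pairs between groups. The SD of the difference between replicates ranged from 0.146 to 0.228 log2 units, so no array was a copy of another. The labels do not say that replicates came from separate embryos or litters, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

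Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2 values. With the same model on all probe sets, the numbers called equalled those of the authors' deposited table, 5987 for OCP4 against OCP1, 5529 against OCP2 and 6675 against OCP3. A single linear model with 1 mean per group was fitted to all 14 arrays, which leaves 10 residual degrees of freedom, and variances were moderated with eBayes at its defaults. P-values were adjusted by Benjamini-Hochberg over the 21734 genes within each comparison, with a threshold of 0.05. The comparisons were CD73+ against CD73- in Thy1- cells (OCP1 minus OCP2) and in Thy1+ cells (OCP4 minus OCP3), Thy1+ against Thy1- in CD73- cells (OCP3 minus OCP2) and in CD73+ cells (OCP4 minus OCP1), both diagonal pairs, the interaction of CD73 and Thy1, and a moderated F-test over all 4 groups. A log2 difference is given with its standard error (SE), and a group level as mean and SD of log2 intensity.

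The lists described next, the rule for named genes and the comparisons were fixed before the data were examined. So were the alternative settings, except the one named as added later. There were 26 lists with 396 entries, of which 394 were matched to a symbol. They cover skeletal lineages (cartilage matrix and chondrocyte, hypertrophic chondrocyte, osteoblast, fibrous connective tissue and perichondrium, tendon and ligament, joint interzone and articular, stromal niche), other cell types (haematopoietic, erythroid, osteoclast, endothelial, pericyte and smooth muscle, skeletal muscle, Schwann and nerve, keratinocyte, adipocyte), and processes (cell cycle, hedgehog, BMP and TGF-beta, Wnt, FGF, limb patterning transcription factors, immediate early and dissociation stress, hypoxia and glycolysis, adenosine handling, interferon response). Each list was tested with camera (preset correlation 0.01), adjusted over the lists within a comparison, and again with a correlation estimated from the data. Members were counted by the limma gene test, adjusted over all genes and over the list alone. In 17 cases, none of them called, the median, mean and camera direction of a list differed in sign. A list score is the mean over members of log2 intensity minus the mean of the group means.

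Named genes follow a rule. For each of the 4 comparisons that change a single marker, they are the sort genes Nt5e, Thy1 and Cd9, the 6 largest differences on each side among genes past the threshold whose arrays did not overlap between groups (leaving out predicted genes and clones), and the 2 largest members past the threshold of each list with at least 3 such members or a camera call. For the interaction they are the 5 largest on each side. Diagonal comparisons name only genes already named. Some genes that the rule names are not reported here, though the counts include them.

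The procedure was tested on simulated data over 21734 genes with known changes. Of the genes changed by a log2 difference of 1, it recovered 99% for OCP1 minus OCP2, 100% for OCP4 minus OCP3, 98% for OCP3 minus OCP2 and 99% for OCP4 minus OCP1. For a log2 difference of 0.5, recovery was 68.7%, 82%, 81% and 85% in the same order. False calls made up 2.30%, 6.06%, 5.64% and 8.74% of the calls. Noise was drawn independently for each gene in a single run per comparison, which gave 174 to 206 calls. Correlated genes and as many changes as in the data were not simulated, so these are not error rates of the real calls. Alternatives covered dim genes, probe set choice, normalization, centring, the variance prior, array weights, the arrays in the fit, a replicate block, thresholds, set tests and leaving out each array. An alternative added later left out genes of lists of other cell types and genes correlated with the scores of those lists. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.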

Results

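The arrays profiled cells sorted as osteochondroprogenitors, skeletal precursor cells that can give rise to cartilage and bone, from mouse limbs at embryonic day 16.5. Whether the sorted cells have that potential was not tested here. The cells carried CD9, a tetraspanin of the cell surface, and were divided by CD73, the surface enzyme that turns extracellular AMP into adenosine, and by Thy1, a surface glycoprotein of mesenchymal cells, neurons and T cells. The 4 groups form a factorial design, with 3 arrays each for OCP1 (CD73+ Thy1-) and OCP2 (CD73- Thy1-) and 4 arrays each for OCP3 (CD73- Thy1+) and OCP4 (CD73+ Thy1+). The series asks which genes differ between these sub-populations. A moderated F-test found 8577 of 21734 genes to differ among the groups. The first principal component held 37.5% of the variance and placed the OCP4 arrays (25.1 to 33.4) apart from all others (-19 to -3.2). The second component held 30.1% and ran from the OCP1 arrays (25.1 to 27.8) to the OCP3 arrays (-22.6 to -20.9).

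The transcripts of the sort markers followed the gates. Nt5e, which encodes CD73, had a log2 intensity of 12.29 ± 0.16 (SD, n = 3) in OCP1 and 13.19 ± 0.16 (SD, n = 4) in OCP4, against 9.30 ± 0.15 (SD, n = 3) in OCP2 and 9.46 ± 0.44 (SD, n = 4) in OCP3. Thy1 stood at 12.60 ± 0.12 in OCP3 and 13.22 ± 0.07 in OCP4, against 9.33 ± 0.11 in OCP1 and 9.60 ± 0.36 in OCP2. Cd9 ranged from 11.52 ± 0.11 in OCP1 to 10.60 ± 0.17 in OCP4, where it was 1.89-fold lower than in OCP1 (limma with Benjamini-Hochberg, adjusted p = 2.01e-06). Within the Thy1+ cells, OCP4 also had 1.53-fold more Thy1 than OCP3 (adjusted p = 0.000992).

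**Figure D1:**
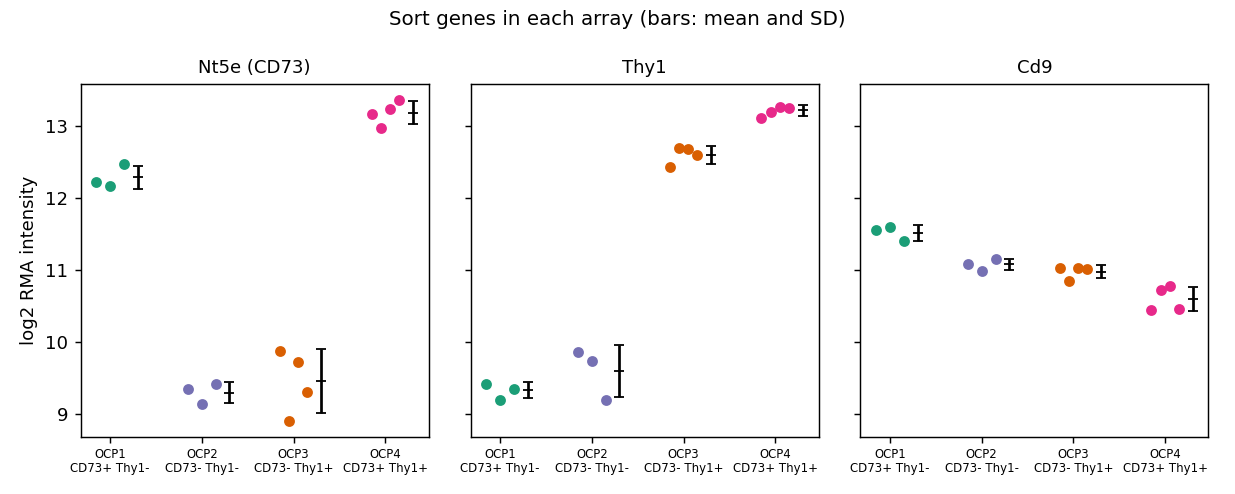
Log2 RMA intensity of Nt5e, Thy1 and Cd9 in each array (points) of the 4 groups, with the group mean and SD as bars. Nt5e means are 12.29 and 13.19 in the CD73+ groups against 9.30 and 9.46 in the CD73- groups, and Thy1 means are 12.60 and 13.22 in the Thy1+ groups against 9.33 and 9.60.

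CD73+ was compared with CD73- among Thy1- cells (OCP1 minus OCP2) to ask how CD73 divides the cells without Thy1. Camera put the cartilage and hypertrophic lists higher in OCP1, and the endothelial, Schwann and muscle lists higher in OCP2. With an estimated correlation the hypertrophic and Schwann calls held, and the cartilage (adjusted p = 0.104), endothelial (adjusted p = 0.0780) and muscle (adjusted p = 0.168) calls did not. Col10a1, the collagen of hypertrophic cartilage, was 12.5-fold higher in OCP1 (13.12 ± 0.27 against 9.48 ± 0.14, SD, n = 3 each; log2 difference 3.65 ± 0.34, SE). Mmp13, a collagenase of late hypertrophic chondrocytes and osteoblasts, was 7.15-fold higher and Panx3, a channel protein of prehypertrophic and hypertrophic chondrocytes, 4.81-fold higher. Loxl4, a lysyl oxidase-like enzyme, was 4.48-fold and Itgbl1 4.17-fold higher. The limma adjusted p-values of these genes ran from 6.08e-09 to 1.84e-05.

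Of 24 cartilage matrix genes, 17 were higher in OCP1 and 0 lower (24 and 0 adjusted over the list alone), led by the matrix protein gene Comp (2.88-fold) and 3110079O15Rik (2.84-fold), the file's name for Snorc, a cartilage proteoglycan. Camera called the list (adjusted p = 1.49e-19), but not with a correlation taken from the data (adjusted p = 0.104 with an estimated correlation). Of 12 hypertrophic genes, 10 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 3.63e-16, and adjusted p = 0.0228 with an estimated correlation). The joint list, with Gdf5, a growth factor of the joint interzone (2.24-fold), and Prg4, which encodes lubricin (2.08-fold), had 6 of 11 members higher and 0 lower (7 and 0 adjusted over the list alone; adjusted p = 0.0228 with an estimated correlation). The Wnt list had 14 of 21 higher and 0 lower (15 and 1 adjusted over the list alone; adjusted p = 0.0228 with an estimated correlation), among them the Wnt inhibitor Wif1 (2.30-fold) and the receptor Lgr5 (2.15-fold).

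Osteoblast genes were higher in 9 of 18 cases and lower in 1 (10 and 1 adjusted over the list alone), led by Spp1, which encodes osteopontin (3.75-fold), and Smpd3 (3.67-fold); camera gave adjusted p = 2.64e-08 and adjusted p = 0.0538 with an estimated correlation. Tendon genes were higher in 7 of 10 cases, with Kera (1.81-fold) and Fmod (1.66-fold), and 0 were lower (8 and 1 adjusted over the list alone; adjusted p = 0.155 with an estimated correlation). Of the fibrous list 8 of 24 were higher (12 adjusted over the list alone), with Twist2 (1.72-fold) and Twist1 (1.54-fold), and adjusted p = 0.168 with an estimated correlation. BMP and TGF-beta genes (8 of 23 higher, 9 adjusted over the list alone, with Bmp2 and Bmp6), hypoxia genes (5 of 16 higher and 1 lower, 6 and 1 adjusted over the list alone, with Car9 at 2.72-fold) and limb patterning factors (4 of 20 higher, 5 and 1 lower adjusted over the list alone, with Hoxa11 and Pitx1) were also called upward by camera. Their adjusted p-values with an estimated correlation were 0.124, 0.126 and 0.168. Dissociation stress genes moved with the same side: 8 of 16 were higher in OCP1 (9 adjusted over the list alone), with Fosb 1.42-fold and Dusp1 1.39-fold (adjusted p = 0.168 with an estimated correlation). The hedgehog list was called upward by camera (adjusted p = 0.0445; adjusted p = 0.335 with an estimated correlation), with Ptch1 1.29-fold higher; 2 of 10 members were higher and 1 lower (3 and 1 adjusted over the list alone).

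On the OCP2 side, 13 of 14 endothelial genes were higher than in OCP1 (13 adjusted over the list alone), among them the vascular cadherin gene Cdh5 (12.51 ± 0.34 against 10.60 ± 0.22, SD, n = 3 each; 3.75-fold) and Pecam1 (3.68-fold). Camera gave adjusted p = 1.80e-16, and adjusted p = 0.0780 with an estimated correlation. Endothelial genes outside the list, Prnd (5.52-fold, with a dimmer probe set at a log2 difference of 0.15) and Cd93 (4.62-fold), were among the largest differences, along with Eltd1 (3.95-fold) and the chemokine gene Cxcl13 (3.84-fold). Schwann and nerve genes were higher in OCP2 in 10 of 12 cases (10 adjusted over the list alone, with 1 the other way; camera adjusted p = 2.04e-11, and adjusted p = 0.0423 with an estimated correlation), with Gfra3 (3.45-fold). Skeletal muscle genes were higher in 10 of 18 cases (15 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation), with Myh3 (2.18-fold) and Myf5 (1.83-fold). Pericyte genes were higher in 5 of 10 cases and lower in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.176 with an estimated correlation), with Rgs5 (4.02-fold) and Acta2 (2.70-fold). The camera calls for adipocyte (Cd36 2.74-fold, Fabp4 2.22-fold; 2 of 8, and 2 adjusted over the list alone), cell cycle (6 of 24, 8 adjusted over the list alone, with Ccnb1 and Birc5) and interferon genes (3 of 11, 4 adjusted over the list alone, with Oasl2 and Rsad2) also lay on the OCP2 side. Their adjusted p-values with an estimated correlation were 0.301, 0.147 and 0.124.

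Lists without a camera call still had members past the threshold. In the adenosine list, Entpd1 (2.98-fold) and Entpd2 (2.14-fold), which encode enzymes that hydrolyse extracellular nucleotides, were higher in OCP2; 2 of 12 members were higher in OCP1 and 4 in OCP2 (3 and 4 adjusted over the list alone). The stromal niche genes Nes (1.94-fold) and Mcam (1.91-fold) were higher in OCP2, while the FGF list held Fgf9 (1.94-fold higher in OCP1) and Dusp6 (1.68-fold higher in OCP2), and the osteoclast list Ctsk (1.62-fold higher in OCP1) and Mmp9 (1.53-fold higher in OCP1). Haematopoietic, erythroid and keratinocyte lists had 0, 0 and 1 members past the threshold and no camera call (adjusted p = 0.0962, 0.133 and 0.0864).

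In all, limma with Benjamini-Hochberg adjustment called 2388 genes between OCP1 and OCP2, with 963 higher and 1425 lower in OCP1, and 173 of them differed at least 2-fold. With arrays centred on their medians, the split was 1531 higher and 976 lower. The count was 1477 without OCP1 replicate 1 and 1486 without OCP2 replicate 2. The Birc5 call was lost with the replicate block (limma adjusted p = 0.0672), quantile normalization run again (0.071) and only the arrays of the 2 groups (0.089). Left-out arrays ended the calls for Birc5 (any OCP1 array, OCP2 replicate 2 or 3, OCP3 replicate 1, 3 or 4; adjusted p up to 0.160, and 0.136 with arrays centred on their medians), Kera (OCP1 replicate 2 or 3, OCP2 replicate 1 or 2; up to 0.0668), Ptch1 (OCP1 replicate 1, OCP2 replicate 2 or 3; up to 0.0791) and Fabp4 (OCP1 replicate 1 or OCP2 replicate 2; up to 0.0508). Thy1, at -0.28 ± 0.13 (SE) log2 units with adjusted p = 0.233, passed only without OCP2 replicate 3 (adjusted p = 0.00436).

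**Figure D2:**
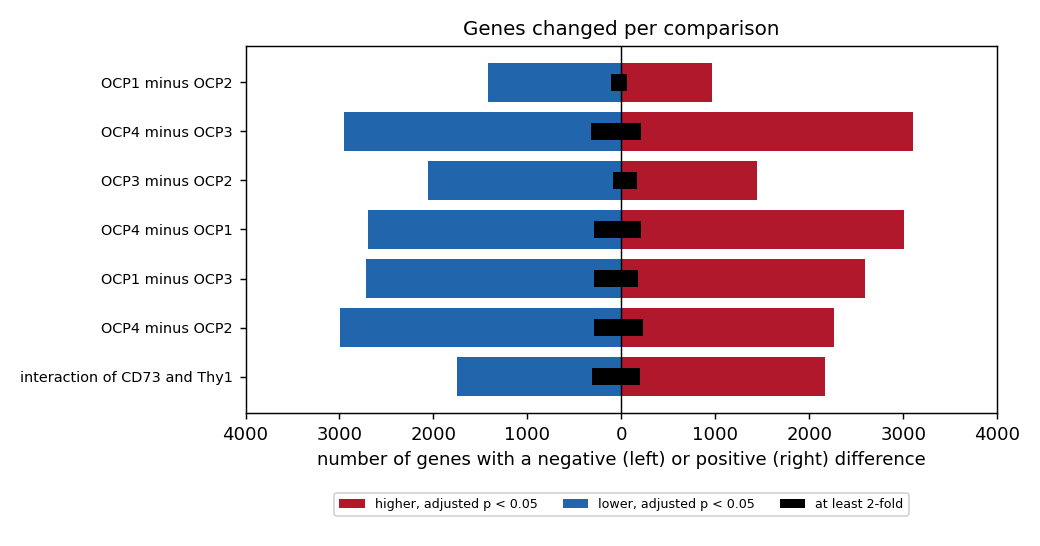
Number of genes with limma adjusted p under 0.05 per comparison (x axis), with positive differences to the right and negative ones to the left; black bars count those of at least 2-fold. The bars run from 963 higher and 1425 lower genes for OCP1 minus OCP2 to 3097 higher and 2949 lower genes for OCP4 minus OCP3.

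Among Thy1+ cells, CD73+ (OCP4) was compared with CD73- (OCP3). Camera put the pericyte, osteoblast and Schwann lists higher in OCP3 and the Wnt list higher in OCP4. With an estimated correlation only the pericyte call held, and adjusted p = 0.191 for the osteoblast and Schwann lists and adjusted p = 0.278 for the Wnt list. Rgs5, a pericyte marker, was 13.4-fold lower in OCP4 (9.53 ± 0.43 against 13.28 ± 0.17, SD, n = 4 each; log2 difference -3.75 ± 0.16, SE). Fhl5 (14.1-fold), the olfactory receptor gene Olfr558 (13.4-fold), Lgi1 (10.1-fold), the adrenergic receptor gene Adra2a (8.32-fold) and Gucy1a3, a subunit of the nitric oxide receptor (7.73-fold), were lower too. Higher in OCP4 were Cldn10, a tight junction claudin (log2 difference 3.45 ± 0.12, SE), Cntn4, a neuronal contactin (8.75-fold), and Lix1 (7.64-fold). The limma adjusted p-values of these genes lay between 9.53e-12 and 2.10e-09.

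All 10 pericyte and smooth muscle genes were lower in OCP4 (10 adjusted over the list alone), including Myh11, smooth muscle myosin (6.92-fold). Camera gave adjusted p = 3.69e-13, and adjusted p = 0.0300 with an estimated correlation. This was the only list of the comparison whose call held with an estimated correlation. Pericytes inside the OCP3 gate cannot be told apart here from higher expression of these genes by other OCP3 cells. Of 18 osteoblast genes, 12 were lower and 1 higher (13 and 2 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation), with the alkaline phosphatase gene Alpl 3.79-fold lower and the homeobox gene Dlx5 3.77-fold lower. Schwann and nerve genes were lower in 9 of 12 cases and higher in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation), with Fabp7 5.69-fold and Cdh19 3.68-fold lower. In the stromal niche list 8 of 14 were lower and 3 higher (8 and 3 adjusted over the list alone; adjusted p = 0.175 with an estimated correlation), with Mcam (4.52-fold lower) and Angpt1 (3.32-fold lower). Tendon genes were lower in 5 of 10 cases and higher in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.592 with an estimated correlation), with Tnc and Thbs4. Of 14 endothelial genes 6 were lower and 1 higher (7 and 1 adjusted over the list alone; adjusted p = 0.687 with an estimated correlation): Esam was 4.39-fold lower and Sox18, an endothelial transcription factor, 2.41-fold higher.

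The Wnt list leaned towards OCP4, with 13 of 21 higher and 5 lower (13 and 6 adjusted over the list alone; camera adjusted p = 0.000260, and adjusted p = 0.278 with an estimated correlation). The Wnt antagonist gene Dkk1 was 6.25-fold higher (12.16 ± 0.10 against 9.52 ± 0.14, SD, n = 4 each) and the Wnt effector gene Lef1 3.61-fold higher. Of 24 fibrous genes 16 were higher and 6 lower (16 and 6 adjusted over the list alone; adjusted p = 0.687 with an estimated correlation), led by Twist2 (4.46-fold) and Twist1 (2.00-fold). Hedgehog genes were higher in 7 of 10 cases and lower in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.429 with an estimated correlation), with Cdon 1.72-fold higher and Hhip 2.13-fold lower. Cell cycle genes were higher in 10 of 24 cases (10 adjusted over the list alone; adjusted p = 0.687 with an estimated correlation), with E2f1 (1.39-fold) and Tyms (1.24-fold). Haematopoietic genes moved with these groups: 6 of 19 were higher in OCP4 (6 adjusted over the list alone; adjusted p = 0.687 with an estimated correlation), with Cd53 (1.58-fold) and Fcer1g (1.52-fold).

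Other lists were not called as sets but had members far apart. Col10a1 (5.27-fold) and the parathyroid hormone receptor gene Pth1r (2.57-fold) were higher in OCP4, with 4 of 12 hypertrophic genes higher and 4 lower (5 and 4 adjusted over the list alone). Cartilage matrix genes divided into 6 higher and 5 lower of 24 (6 and 5 adjusted over the list alone), with Sox5 2.12-fold lower and Matn1 1.76-fold higher. Bmp5 was 4.05-fold and its receptor gene Bmpr1b 2.33-fold lower in OCP4, and Mmp9, a gelatinase, 3.53-fold lower. The homeobox genes Hoxd8 (2.54-fold) and Meis1 (2.21-fold), Fgf10 (2.11-fold), the joint factor Erg (2.00-fold) and the interferon-induced Ifit2 (1.99-fold) were higher, and Spry4 (2.40-fold) and Egr2 (1.79-fold) lower. Ctsk, Wnt4, Ifit3, Entpd1, Car9, Rhd and Epor were higher by 1.27-fold to 1.88-fold, and Entpd2, Socs3 and Ankrd37 lower by 1.28-fold to 1.93-fold. Keratinocyte and skeletal muscle lists had 0 and 2 members past the threshold.

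Limma with Benjamini-Hochberg adjustment called 6046 genes, 3097 higher and 2949 lower in OCP4, of which 526 differed at least 2-fold. Centring arrays on their medians gave 4134 higher and 2550 lower. The Matn1 call was lost with the replicate block (limma adjusted p = 0.0756), the alternative variance prior (0.0806) and only the arrays of the 2 groups (0.0928). That for Cd53 was lost with the alternative variance prior (0.0632), only the arrays of the 2 groups (0.0590) and array weights (0.0617). Left-out arrays ended the calls for Cd53 (any OCP1 array, OCP2 replicate 3, OCP3 replicate 1 or 3, OCP4 replicate 2, 3 or 4; adjusted p up to 0.149), Matn1 (OCP1 replicate 1 or 3, OCP2 replicate 2 or 3, OCP3 replicate 2, 3 or 4, OCP4 replicate 2 or 3; up to 0.126) and Fcer1g (OCP3 replicate 3 or OCP4 replicate 2; up to 0.0527).

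Thy1+ was then compared with Thy1- among CD73- cells (OCP3 minus OCP2). Camera put the cartilage list lower and the pericyte and osteoblast lists higher in OCP3 than in OCP2. None of these calls held with an estimated correlation (adjusted p = 0.153 for cartilage and osteoblast, and adjusted p = 0.0503 for pericyte genes). Matn1, a matrilin of cartilage, was 7.16-fold lower (9.89 ± 0.59, SD, n = 4, against 12.73 ± 0.06, SD, n = 3). The cartilage genes Clec3a (5.33-fold), Matn3 (5.22-fold), Lect1, which encodes chondromodulin (4.91-fold), and Scrg1 (4.54-fold) were lower as well, as was the protease inhibitor gene Serpina3n (4.53-fold). Besides Thy1 itself (8.02-fold), Adra2a (10.7-fold), Fhl5 (10.6-fold), Mmp13 (7.45-fold), the carboxypeptidase gene Cpa1 (7.11-fold) and Mmp9 (6.98-fold) were higher in OCP3. The limma adjusted p-values of these genes ran from 1.08e-10 to 2.54e-05. Nt5e differed by 0.15 ± 0.18 (SE) and Cd9 by -0.09 ± 0.09 log2 units, and neither passed.

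Of 24 cartilage matrix genes, 22 were lower in OCP3 and 0 higher (23 and 0 adjusted over the list alone; camera adjusted p = 4.29e-21, and adjusted p = 0.153 with an estimated correlation). Pericyte and smooth muscle genes were higher in 7 of 10 cases (8 adjusted over the list alone; camera adjusted p = 1.30e-11, and adjusted p = 0.0503 with an estimated correlation), with Rgs5 (6.49-fold) and the potassium channel gene Kcnj8 (4.32-fold). Osteoblast genes were higher in 9 of 18 cases and lower in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.153 with an estimated correlation), with Alpl (3.91-fold) and Sp7, the osteoblast factor osterix (3.18-fold). Stromal niche genes were higher in 7 of 14 cases and lower in 1 (7 and 2 adjusted over the list alone; adjusted p = 0.0847 with an estimated correlation), with Mcam (2.03-fold) and Ly6a, which encodes Sca-1 (2.02-fold). Dissociation stress genes were higher in 4 of 16 cases (5 adjusted over the list alone; adjusted p = 0.574 with an estimated correlation), with Hspa1a and Atf3.

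Skeletal muscle genes were lower in OCP3 in 13 of 18 cases and higher in 1 (17 and 1 adjusted over the list alone; adjusted p = 0.338 with an estimated correlation), with Myh3 (2.29-fold) and the satellite cell factor Pax7 (1.87-fold). Adipocyte genes were lower in 6 of 8 cases (7 adjusted over the list alone; adjusted p = 0.396 with an estimated correlation), with Adipoq (2.68-fold) and Fabp4 (1.82-fold). Endothelial genes were lower in 6 of 14 cases and higher in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.574 with an estimated correlation), with Robo4 (2.29-fold) and Pecam1 (2.10-fold). Joint genes (7 of 11 lower and 1 higher, 7 and 2 adjusted over the list alone, with Prg4 at 2.39-fold and Dcx at 2.36-fold) and tendon genes (6 of 10 lower and 1 higher, 7 and 1 adjusted over the list alone, with Scx, the tendon lineage factor, at 2.07-fold, and Kera) were lower too. Their adjusted p-values with an estimated correlation were 0.243 and 0.338. So were hypoxia genes (7 of 16, 10 adjusted over the list alone, with Bnip3 and Car9) and limb patterning factors (8 of 20, 10 and 1 higher adjusted over the list alone, with the hindlimb factors Pitx1, at 1.63-fold, and Tbx4, at 1.60-fold). Their adjusted p-values with an estimated correlation were 0.243 and 0.338.

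Of the lists without a camera call, the fibrous list held Pdgfrb, a growth factor receptor gene of mesenchyme and pericytes (2.63-fold higher), and Prrx1 (1.55-fold higher). Hhip (2.71-fold), Rspo3 (1.79-fold), Fgfr2 (1.74-fold), Tgfb1 (1.43-fold) and Ifit3 (1.35-fold) were higher in OCP3. Foxa3 (3.08-fold), Entpd1 (2.31-fold), the Wnt antagonist Frzb (1.87-fold), Cdon (1.64-fold), Etv5 (1.58-fold), Rsad2 (1.49-fold), Bmp4 (1.43-fold), Enpp1 (1.40-fold) and Calcr (1.28-fold) were lower. The Schwann and nerve list had 1 of 12 members higher and 1 lower (1 and 2 adjusted over the list alone), with a median difference of -0.11 log2 units (camera adjusted p = 0.621).

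Limma with Benjamini-Hochberg adjustment called 3502 genes, 1442 higher and 2060 lower in OCP3, and 259 differed at least 2-fold (165 higher and 94 lower). Centring arrays on their medians gave 1695 higher and 1534 lower. With the replicate block the call for Enpp1 was lost (limma adjusted p = 0.0558). With only the arrays of the 2 groups those for Kera (0.0714) and Atf3 (0.0523) were lost. Without OCP2 replicate 2 the calls for Adipoq (adjusted p = 0.0852), Atf3 (0.0564), Hspa1a (0.0559) and Fabp4 (0.103) were lost, and without OCP2 replicate 3 those for Kera (0.0779), Ifit3 (0.0577) and Enpp1 (0.0507). Fabp4 was also lost without OCP2 replicate 1 (0.0800) or OCP3 replicate 1 or 3 (up to 0.0642), and Enpp1 without OCP2 replicate 1 (0.0778).

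Among CD73+ cells, Thy1+ (OCP4) was compared with Thy1- (OCP1). Every cartilage matrix and tendon gene on the lists was lower in OCP4. The cartilage genes Clec3a (8.60-fold), Epyc (7.59-fold), Scrg1 (7.31-fold), Comp (6.99-fold) and Matn1 (6.97-fold), and the lubricin gene Prg4 (7.64-fold), had the largest differences, with Comp at 10.03 ± 0.39 (SD, n = 4) against 12.84 ± 0.13 (SD, n = 3). Higher in OCP4, besides Thy1 (14.8-fold), were Cldn10 (10.6-fold), the neuronal stathmin gene Stmn2 (8.35-fold), Cntn4 (8.06-fold), the phospholipase gene Pla2g4c (7.50-fold) and the Iroquois factor gene Irx1 (7.36-fold). The limma adjusted p-values of these genes ran from 6.83e-11 to 6.18e-06.

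The cartilage matrix list had 24 of 24 members lower (24 adjusted over the list alone; camera adjusted p = 1.45e-28) and the tendon list 10 of 10 (10 adjusted over the list alone; camera adjusted p = 1.39e-11), with the tendon factors Mkx (3.55-fold) and Scx (2.79-fold). For both lists, adjusted p = 0.0717 with an estimated correlation. The joint list had 9 of 11 lower and 1 higher (9 and 1 adjusted over the list alone), with Gdf5 3.56-fold lower, and the hypoxia list 13 of 16 lower and 1 higher (13 and 1 adjusted over the list alone), with Car9 3.11-fold and Bnip3 2.52-fold lower. For these 2 lists too, adjusted p = 0.0717 with an estimated correlation. Of 12 hypertrophic genes 7 were lower and 3 higher (8 and 3 adjusted over the list alone), with Col10a1 (5.27-fold) and Panx3 (4.53-fold) lower. Of 18 osteoblast genes 10 were lower and 2 higher (10 and 2 adjusted over the list alone), with Spp1 4.90-fold and Smpd3 3.98-fold lower, and of 23 BMP and TGF-beta genes 13 were lower and 4 higher (16 and 4 adjusted over the list alone), with Bmp5 3.15-fold and Bmpr1b 2.61-fold lower. The adjusted p-values with an estimated correlation were 0.292, 0.200 and 0.200. Limb patterning factors were lower in 12 of 20 cases and higher in 5 (12 and 6 adjusted over the list alone; adjusted p = 0.648 with an estimated correlation), with Tbx4 3.29-fold and Pitx1 2.76-fold lower.

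Cell cycle genes were higher in OCP4 in 21 of 24 cases and lower in 0 (22 and 0 adjusted over the list alone; camera adjusted p = 8.34e-11, and adjusted p = 0.0809 with an estimated correlation), by small amounts: Bub1, a mitotic checkpoint kinase gene, was 1.54-fold and Birc5 1.39-fold higher. Fibrous genes were higher in 8 of 24 cases and lower in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.804 with an estimated correlation), with Twist2 at 3.77-fold and Twist1 at 1.77-fold. The endothelial, haematopoietic and erythroid lists moved the same way. Endothelial genes were higher in 6 of 14 cases (7 adjusted over the list alone), with Sox18 (4.25-fold) and Cdh5 (1.64-fold). Haematopoietic genes were higher in 6 of 19 cases (9 adjusted over the list alone), with Lyz2 (1.76-fold) and Cd53 (1.69-fold). Erythroid genes were higher in 6 of 12 cases (7 adjusted over the list alone), with Hbb-b1 (1.55-fold). For each of these 3 lists, adjusted p = 0.648 with an estimated correlation. The median member of the haematopoietic list (7.43 in OCP1 and 7.69 in OCP4) and of the erythroid list (8.23 and 8.34) lay under the median level of all genes, 9. Pericyte and smooth muscle genes did not move with them, with 3 of 10 higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.766).

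Other lists were not called by camera. In the Wnt list 11 of 21 were higher and 9 lower (11 and 9 adjusted over the list alone), with Dkk1 (6.38-fold) and the Wnt effector Tcf7 (3.19-fold) higher. The hedgehog target Gli1 (1.87-fold) was higher, as were Entpd1 (2.42-fold), Tnfrsf11a (1.95-fold), Rgs5 (1.94-fold) and Mmp9 (1.30-fold). Enpp1, a pyrophosphatase that limits mineral deposition (4.22-fold), the stromal factors Foxc1 (3.33-fold) and Ebf3 (2.29-fold), Fgf18 (2.33-fold), Cspg4 (1.87-fold), Fgf9 (1.76-fold), Egr2 (1.68-fold) and Socs3 (1.57-fold) were lower. Skeletal muscle and Schwann lists each had 1 member higher, and 0 and 1 lower.

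Limma with Benjamini-Hochberg adjustment called 5706 genes, 3005 higher and 2701 lower in OCP4, and 510 differed at least 2-fold. With the alternative variance prior the calls for Cd53 (limma adjusted p = 0.0532) and Hbb-b1 (0.0536) were lost. With only the arrays of the 2 groups that for Mmp9 was lost (0.0764). The calls for Cd53, Hbb-b1 and Mmp9 were lost without OCP1 replicate 3 (adjusted p = 0.120, 0.147 and 0.138) and without OCP4 replicate 2 or 3. Cd53 and Hbb-b1 were also lost without OCP1 replicate 1 (0.149 and 0.0750), Mmp9 without OCP1 replicate 2 (0.0974) and Cd53 without OCP4 replicate 4 (0.0503).

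**Figure D3:**
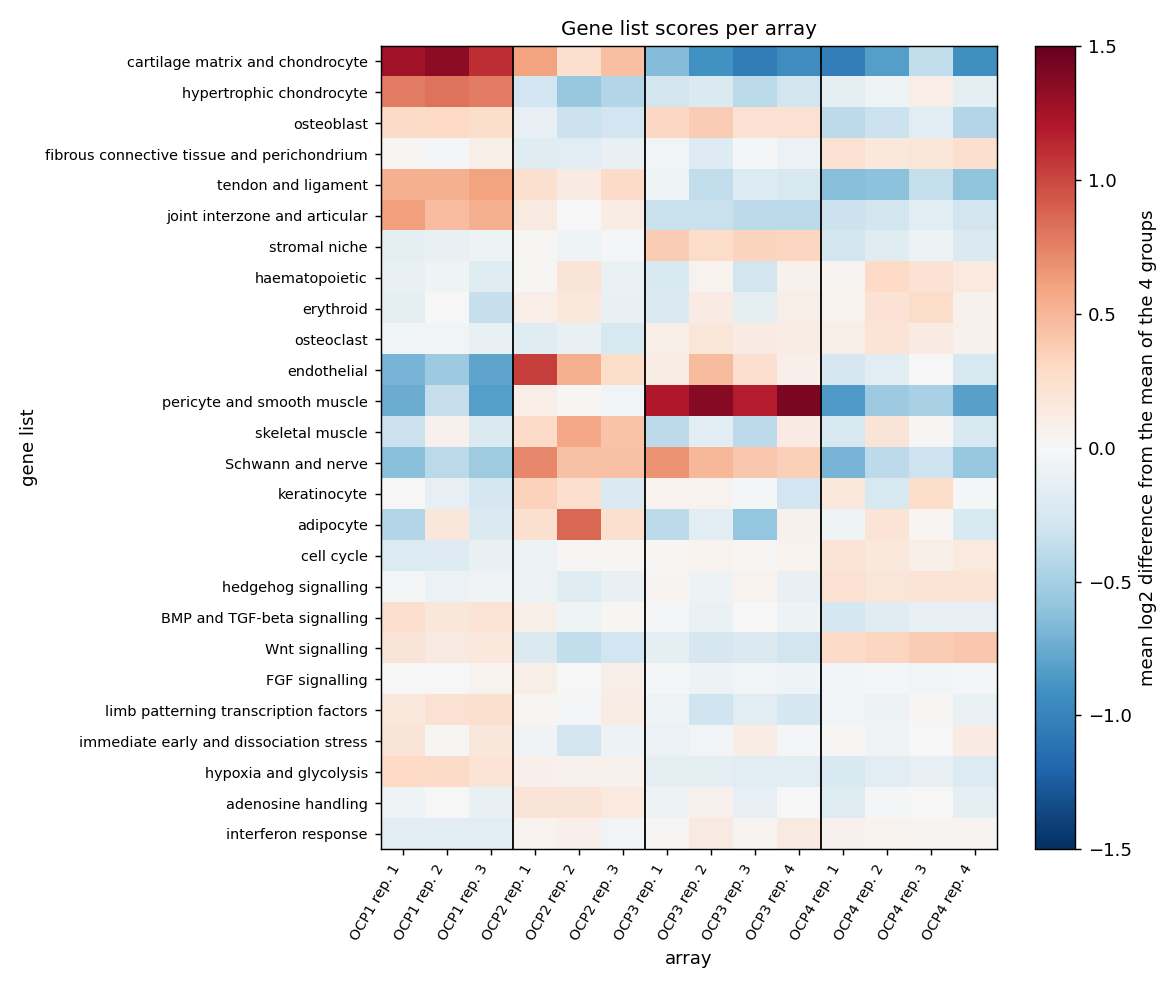
Score of each of the 26 gene lists (rows) in each array (columns), as the mean log2 difference of its members from the mean of the 4 groups; red is higher and blue lower, and vertical lines separate the groups. Mean cartilage scores are 1.24 in OCP1, 0.43 in OCP2, -0.88 in OCP3 and -0.79 in OCP4, and the pericyte score is 1.29 in OCP3 against 0.03 or less in the other groups.

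The diagonal comparisons change both markers. OCP1 minus OCP3 gave 5309 genes (2596 higher and 2713 lower, 468 of at least 2-fold) by limma with Benjamini-Hochberg adjustment, and 3002 higher and 2388 lower with arrays centred on their medians. All 24 cartilage genes were higher in OCP1 (24 adjusted over the list alone; camera adjusted p = 1.50e-27, and adjusted p = 0.0774 with an estimated correlation), and outside that list Col10a1 was 27.8-fold and Clec3a 19.3-fold higher. Pericyte genes were lower in 8 of 10 cases and higher in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.0499 with an estimated correlation), with Rgs5 26.1-fold lower, and joint genes were higher in 8 of 11 and lower in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0499 with an estimated correlation). OCP4 minus OCP2 gave 5251 genes (2258 higher and 2993 lower, 520 of at least 2-fold), and 3753 higher and 2287 lower with arrays centred on their medians. All 24 cartilage genes were lower in OCP4 (24 adjusted over the list alone; camera adjusted p = 2.40e-17, and adjusted p = 0.205 with an estimated correlation), and Cldn10 (12.3-fold), Dkk1 (9.78-fold) and Twist2 (6.48-fold) were higher.

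The CD73 difference was set side by side in the Thy1- and Thy1+ cells, which share no arrays, though the fit gave them a common variance per gene. That common variance, and genes too dim to be called in either, can raise the overlap over that of independent lists. Of the genes called in both, 385 were higher with CD73 in both and 632 lower in both, against 137.2 and 193.4 for independent lists, while 403 went opposite ways, against 333.7. Nt5e, Loxl4 and Col10a1 were higher with CD73, and Rgs5 lower, on both sides. Across genes the log2 differences correlated with r = 0.30 (Spearman 0.17); genes are not independent replicates. The Thy1 difference, in CD73- and in CD73+ cells, was higher in both for 587 genes and lower in both for 861, against 199.4 and 256 for independent lists. It went opposite ways for 442, against 464, with r = 0.32 across genes (Spearman 0.21).

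**Figure D4:**
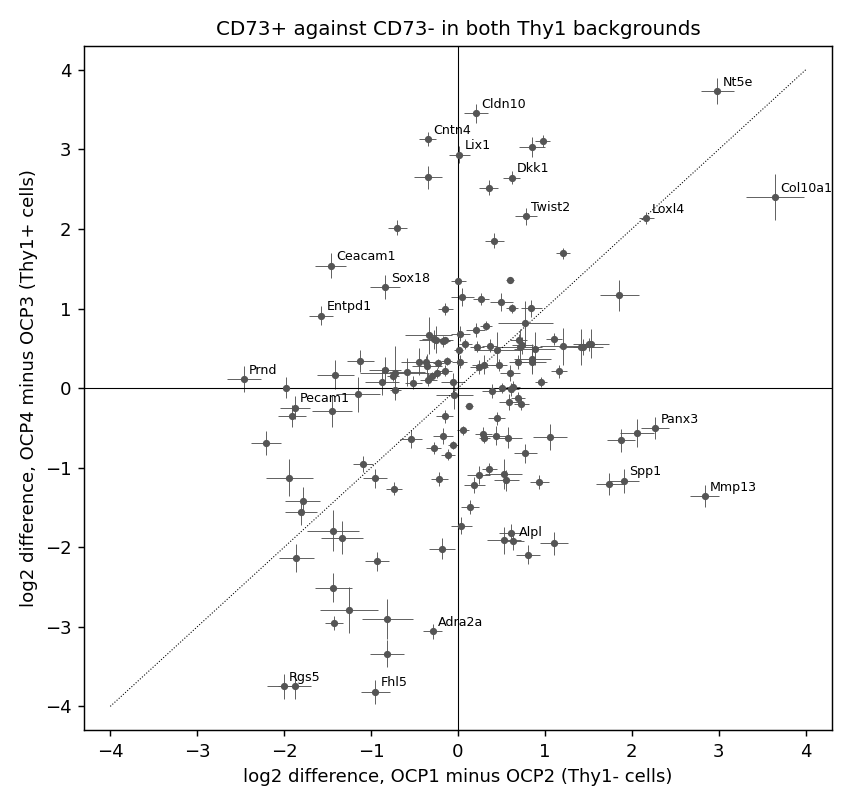
Log2 difference between CD73+ and CD73- cells for the named genes, in Thy1- cells (x axis, OCP1 minus OCP2) and in Thy1+ cells (y axis, OCP4 minus OCP3), with SE bars; the dotted line marks equal differences. Mmp13 lies at 2.84 and -1.36, Cntn4 at -0.35 and 3.13, and Nt5e at 2.98 and 3.73.

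The interaction tested whether the CD73 difference depended on Thy1, as the difference in Thy1+ cells minus that in Thy1- cells. Limma with Benjamini-Hochberg adjustment called 3915 genes, 2165 with a positive and 1750 with a negative value, and 514 reached a log2 value of 1 in size. With arrays centred on their medians, 1862 were positive and 1879 negative. The largest positive values belonged to Cntn4 (3.48 ± 0.13, SE; adjusted p = 2.34e-09), Cldn10 (3.25 ± 0.18), the adhesion molecule gene Ceacam1 (3.01 ± 0.24), Pla2g4c (2.99 ± 0.21) and Lix1 (2.92 ± 0.16). Of these, Cldn10, Cntn4, Pla2g4c and Lix1 had means of 10.23 to 11.72 in OCP4 and of 7.33 to 9.06 in the other groups. The largest negative values belonged to Mmp13 (-4.19 ± 0.22), Spp1 (-3.07 ± 0.23), Ostn, which encodes the bone-derived peptide osteocrin (-3.05 ± 0.22), the tenascin gene Tnn (-2.95 ± 0.21) and Omd, the bone proteoglycan osteomodulin (-2.90 ± 0.19). Mmp13 was high in OCP1 (11.37 ± 0.15) and OCP3 (11.43 ± 0.15) and low in OCP2 (8.54 ± 0.18), with OCP4 between these levels. Osteoblast genes were negative in 10 of 18 cases and positive in 0 (12 and 1 adjusted over the list alone), and pericyte genes negative in 9 of 10 (9 adjusted over the list alone). For both lists, adjusted p = 0.0347 with an estimated correlation, and these were the only camera calls of the interaction to hold with it, out of 17.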

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

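The tests of explanations for the endothelial, Schwann and muscle genes in OCP2 were chosen only after the result was seen. The CD73 difference depended on Thy1 for 109 of 150 named genes and 17 of 26 lists, by the limma interaction with Benjamini-Hochberg adjustment and by camera. All named genes but the 3 sort genes were picked for large differences, 10 of them for large interaction values, and over all genes 3915 of 21734 passed. Of the 17 camera calls, only those for osteoblast and pericyte genes held with an estimated correlation (adjusted p = 0.0347 for both). Each value is the log2 CD73 difference in Thy1+ cells minus that in Thy1- cells.

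Skeletal genes gave mostly negative values. In the cartilage and hypertrophic lists these were Comp (-0.96), 3110079O15Rik (-0.96), Sox5 (-1.61), Panx3 (-2.77) and Mmp13 (-4.19), the last also a gene of osteoblasts. Pth1r, the parathyroid hormone receptor gene, was positive at 0.76. Osteoblast genes were negative: Spp1 (-3.07), Smpd3 (-2.53), Alpl (-2.56), Dlx5 (-2.44) and Sp7 (-2.12). The tendon list gave Fmod (-0.93), Tnc (-1.38), Thbs4 (-0.48) and Mkx (-1.20), and the joint list Gdf5 (-0.95), Prg4 (-1.68) and Wnt4 (0.53). Stromal genes were negative for Mcam (-1.24), Angpt1 (-1.77), Foxc1 (-1.72) and Ebf3 (-0.93), and in the fibrous list Twist2 stood at 1.38, Twist1 at 0.38, Pdgfrb at -0.66 and Prrx1 at -0.35.

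Pericyte and smooth muscle genes were negative, with Rgs5 (-1.74), Myh11 (-1.54), Kcnj8 (-1.64) and Cspg4 (-0.94), and so was the Schwann gene Fabp7 (-1.07). Endothelial genes were positive: Cdh5 (1.55), Pecam1 (1.63), Robo4 (1.58) and Sox18 (2.11). Muscle genes Myh3 (1.47), Myf5 (0.96) and Pax7 (1.07), adipocyte genes Cd36 (1.16) and Fabp4 (1.07), blood genes Fcer1g (0.86) and Epor (0.47) and cell cycle genes Ccnb1 (0.45), Birc5 (0.43), E2f1 (0.47), Tyms (0.54) and Bub1 (0.37) were positive too. Osteoclast-list genes were positive for Tnfrsf11a (0.76) and Calcr (0.45) and negative for Mmp9 (-2.43).

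Among signalling genes, the BMP list gave Bmp2 (-0.81), Bmp6 (-0.62), Bmp5 (-1.83), Bmpr1b (-1.41) and Bmp4 (0.74). The Wnt list gave Dkk1 (2.03), Lef1 (1.44), Tcf7 (0.85), Wif1 (0.49) and Lgr5 (-0.49), the FGF list Fgf9 (-0.87), Fgf18 (-0.86), Spry4 (-0.52), Fgf10 (0.58), Dusp6 (0.90) and Etv5 (0.69), and the hedgehog list Hhip (-1.33), Cdon (0.47) and Gli1 (0.47). Patterning factors gave Pitx1 (-0.76), Tbx4 (-1.04), Hoxd8 (1.34) and Meis1 (1.09), stress genes Fosb (-0.50), Egr2 (-0.72), Socs3 (-0.59) and Atf3 (-0.42), hypoxia genes Car9 (-0.92) and Bnip3 (-0.61), interferon genes Rsad2 (0.58), Ifit2 (1.14) and Ifit3 (0.65) and genes of adenosine handling Entpd1 (2.48) and Enpp1 (-1.60). Of named genes in none of the lists, Cntn4 (3.48), Cldn10 (3.25), Ceacam1 (3.01), Pla2g4c (2.99), Lix1 (2.92), Stmn2 (2.71), Prnd (2.58), Irx1 (2.17), Eltd1 (1.99), Cd93 (1.52) and Thy1 (0.89) were positive, and Ostn (-3.05), Tnn (-2.95), Omd (-2.90), Fhl5 (-2.87), Adra2a (-2.77), Itgbl1 (-2.62), Lgi1 (-2.52), Cpa1 (-2.09), Olfr558 (-1.86), Gucy1a3 (-1.52) and Cd9 (-0.82) negative.

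For lists, the value is the median over members. It was negative for the lists cartilage matrix and chondrocyte (-0.66), hypertrophic chondrocyte (-0.74), osteoblast (-1.17), tendon and ligament (-0.60), joint interzone and articular (-0.07), stromal niche (-0.13), pericyte and smooth muscle (-1.21), BMP and TGF-beta signalling (-0.24), immediate early and dissociation stress (-0.17) and hypoxia and glycolysis (-0.20). It was positive for haematopoietic (0.43), erythroid (0.38), endothelial (0.87), skeletal muscle (0.77), adipocyte (0.97), cell cycle (0.27) and hedgehog signalling (0.31).

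Single arrays stood apart from the rest of their group of 4 in 16 of 352 tests by Dixon's criterion, and chance gives about 1 in 20. The values are log2 intensities, or a score for a list. In OCP3 replicate 2 these were Cd9 (10.85 against 11.01 to 11.03 in the other arrays), Entpd1 (10.07 against 9.71 to 9.75) and Angpt1 (10.07 against 10.31 to 10.35). OCP3 replicate 3 stood apart for Adra2a (11.54 against 11.81 to 11.84) and Foxa3 (6.95 against 7.34 to 7.38), OCP3 replicate 4 for Fgfr2 (11.69 against 11.88 to 11.92) and OCP3 replicate 1 for Epyc (9.03 against 8.25 to 8.34). OCP4 replicate 3 stood apart for Epyc (9.69 against 8.69 to 8.85), Car9 (8.25 against 7.93 to 7.98), Serpina3n (9.29 against 8.52 to 8.63) and Tnn (10.55 against 9.91 to 10.01), and for the score of the tendon list (-0.36 against -0.64 to -0.60). OCP4 replicate 2 did so for Cldn10 (10.63 against 11.23 to 11.26) and Lix1 (11.42 against 11.78 to 11.85), and OCP4 replicate 4 for Dkk1 (12.31 against 12.09 to 12.12) and Gli1 (11.43 against 11.57 to 11.58).

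Endothelial, Schwann and skeletal muscle genes lay higher in OCP2 than in OCP1, with mean log2 shifts of 1.30 ± 0.23, 1.05 ± 0.11 and 0.59 ± 0.14 (SE). No single OCP2 array accounts for this, since each list kept at least 84.0% of its shift whichever was left out. A lower share of the main cell type, which would raise all other types, stayed undecided. The endothelial shift exceeded the muscle one by 0.71 ± 0.29 (SE). These were picked as the highest and lowest of 4 lists at or above the median level, with the adipocyte list not among those compared. That SE does not allow for the picking, and a lower share need not shift genes of different levels alike on the log2 scale. The endothelial shift also exceeded the haematopoietic one by 1.15 ± 0.22 (SE), but those genes are dim and exclude nothing. Endothelial, Schwann and muscle cells inside the OCP2 gate, which selects for CD9 and against CD73 and Thy1, cannot be told apart from higher expression by the CD73-negative cells themselves: of the 15 brightest members, 15 had higher means in OCP2, among them Cdh5 (12.51 against 10.60), Ngfr (12.67 against 11.86) and Actc1 (13.28 against 12.71), but these belong to the lists in which the pattern was seen, and Tek, Gap43, Actc1, Acta1, Myl1 and Tnnt3 did not pass the limma test.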

How the results depend on the processing

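Leaving out genes of other cell types was chosen after seeing the data and the other alternatives before. The count of genes changed stayed within 1.5 times its value in the 6 comparisons, the interaction and the test over any group under the choices of dim-gene filter, probe sets, variance prior, array weights, normalization and centring. It did so too with only the arrays of the 2 groups, run for the 6 comparisons. Leaving out genes of other cell types was run for the 4 comparisons that change a single marker. It only took 613 genes out of the counts, without a new fit. These were members of the endothelial, pericyte, skeletal muscle, Schwann, haematopoietic and erythroid lists, and genes correlating over 0.9 with a score of these lists. The correlated genes were picked by their profile over the same arrays, so they need not mark those cell types. A move beyond 1.5 times was then out of reach, so that setting does not test robustness. The count furthest from its value of 2388, for OCP1 minus OCP2, was 3494 with array weights. A stricter threshold moved it by construction: at adjusted p under 0.01, limma called 1273 genes for OCP1 minus OCP2, 2064 for OCP3 minus OCP2, 3437 for OCP1 minus OCP3 and 2266 for the interaction. Asking also for a 2-fold difference left 173 genes for OCP1 minus OCP2, 526 for OCP4 minus OCP3, 259 for OCP3 minus OCP2, 510 for OCP4 minus OCP1, 468 for OCP1 minus OCP3, 520 for OCP4 minus OCP2, 514 for the interaction and 1116 for any of the 4 groups. With each array left out in turn, the counts ranged from 1477 to 2516 for OCP1 minus OCP2, 5163 to 6553 for OCP4 minus OCP3, 2622 to 3610 for OCP3 minus OCP2, 4371 to 5901 for OCP4 minus OCP1, 3969 to 5587 for OCP1 minus OCP3, 4478 to 5383 for OCP4 minus OCP2, 3012 to 4218 for the interaction and 7528 to 9129 for any group. OCP1 minus OCP2 moved by over 1.5 times without OCP1 replicate 1 (1477) or OCP2 replicate 2 (1486), where 2 arrays of that group remain; beyond that, the cause was not tested. Without the 613 genes left out by that rule, the counts were 2031 (962 higher and 1069 lower) for OCP1 minus OCP2. They were 5553 for OCP4 minus OCP3, 3110 for OCP3 minus OCP2 and 5553 for OCP4 minus OCP1. The replicate numbers did not pair the arrays throughout: in no pair of groups did all same-numbered arrays deviate together with a correlation over 0.1, and 2 of 14 arrays correlated best with their own number. Between OCP1 and OCP2 alone, however, each array correlated best with its own number (r = 0.083, 0.25 and 0.303), so a pairing there is not excluded. With the number as a block, the counts were 2153 for OCP1 minus OCP2, 5778 for OCP4 minus OCP3, 2901 for OCP3 minus OCP2, 5265 for OCP4 minus OCP1, 4761 for OCP1 minus OCP3, 4767 for OCP4 minus OCP2, 3690 for the interaction and 7817 for any group. The balance of higher and lower genes turned with arrays centred on their medians for OCP1 minus OCP2, OCP3 minus OCP2, OCP1 minus OCP3, OCP4 minus OCP2 and the interaction. It also turned for OCP1 minus OCP3 with array weights, quantile normalization or OCP3 replicate 2 left out, and for OCP4 minus OCP3 at adjusted p under 0.01 or without OCP3 replicate 1, 3 or 4 or OCP4 replicate 2. Among genes of at least 2-fold it was the other way round for OCP4 minus OCP3, OCP3 minus OCP2, OCP4 minus OCP1 and the interaction. In the 4 comparisons that change a single marker and the interaction, no call of a named gene or list reversed. For named genes, 4931 results under alternatives kept their side of the threshold, 77 lost a call and 1 gained it. With the dim-gene filter only 189 of the 230 named-gene results were present, so those on genes under the median level were not checked there. For lists, 2437 kept their side, 97 lost a call, 65 of them with an estimated correlation, and 61 gained it. Of those kept, 1769 came from leaving out 1 array. With an estimated correlation most camera calls were lost. Those that held were 4 of 19 for OCP1 minus OCP2, 1 of 11 for OCP4 minus OCP3 and 0 of 12 for OCP3 minus OCP2. For OCP4 minus OCP1 they were 0 of 13, and for the interaction 2 of 17. A result without a call under both settings counts as kept even where its sign differs. Fry ended 4 camera calls there: hedgehog genes in OCP1 minus OCP2, endothelial genes in OCP4 minus OCP3 and in OCP3 minus OCP2, and stress genes in OCP3 minus OCP2 (adjusted p = 0.230, 0.0585, 0.0707 and 0.187), and in the diagonal comparisons that of stress genes in OCP4 minus OCP2 (adjusted p = 0.120). The cause was not tested. The alternative of using the other deposited table was not run, since that table holds no values per sample. On arrays, background limits what can be read of dim genes, since it narrows their differences.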

Other observations

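The tests of the Mup genes, except the version limited to brighter probe sets, and the counts over other splits of the arrays were chosen only after the result was seen. The Notch, dermal fibroblast, Iroquois and Zic, and hepatocyte lists were not among the 26 lists fixed before the data were examined, and were added later. Nrarp and Hey2, targets of Notch signalling, stood at log2 levels of 10.60 and 11.23 in OCP3 against 8.02 and 10.03 in OCP4, and the receptor gene Notch3, which the pericyte list also holds, at 12.61 against 10.59. These genes were chosen after their values were seen. Of 17 other Notch genes, 6 were lower and 3 higher in OCP4 than in OCP3, with Jag1 at -1.54 and Dll1 at 1.05, and the hypothesis that the set was higher in OCP3 stayed undecided (camera p = 0.0522, adjusted p = 0.139, and adjusted p = 0.594 with an estimated correlation). In OCP1 minus OCP2, 9 of the 17 were lower and 0 higher, with Dll4 at -1.43 and Hey1 at -1.13 (camera adjusted p = 1.12e-05, and adjusted p = 0.0706 with an estimated correlation). Endothelial genes moved the same way there, with 13 of 14 lower and a median of -1.39, and Dll4 and Notch4, among the 9, are themselves expressed in vessels.

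Dermal fibroblast genes, a list added later, were tested as a set in OCP4, under the hypothesis that they were higher there than in OCP3. Of 13 genes, 7 were higher and 2 lower, with Lrig1 at 1.34 and Crabp1 at 0.85 on the log2 scale. The set had camera p = 0.0191, which failed correction over 16 tests (adjusted p = 0.0762, and adjusted p = 0.594 with an estimated correlation). The Iroquois factor genes Irx1 and Irx2, the latter chosen after its values were seen, were higher in OCP4 than in OCP3 by log2 differences of 2.52 and 2.23. Of 7 other Iroquois and Zic genes, Zic1 (1.85) and Irx3 (1.43) were higher in OCP4 than in OCP3 and Zic4 (-0.30) lower. The hypothesis that the set was higher there stayed undecided (camera p = 0.158, adjusted p = 0.294, and adjusted p = 0.594 with an estimated correlation).

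Major urinary protein (Mup) genes, expressed in liver and glands and chosen after their values were seen, were highest in OCP4 for all 10 named Mup probe sets, and lowest in OCP2 for 8. Mup7 stood at 8.19 in OCP1, 6.55 in OCP2, 8.77 in OCP3 and 10.73 in OCP4 (limma adjusted p = 2.31e-06 for OCP4 minus OCP2). RNA of liver cells stayed undecided as a source. From OCP2 to OCP4, 16 hepatocyte genes shifted by 0.14 ± 0.21 (SE) where the Mup genes shifted by 2.32, or 6.04%. All hepatocyte genes but Alb and Trf lay under the median level of all genes, 9, in every group, and dim genes exclude nothing. Apoa1 stood at 8.70 in OCP4 against 8.71 in OCP2. Alb, at 9.39 in OCP4 against 7.89 in OCP2, had a difference that did not pass (limma adjusted p = 0.311). No single array of OCP2 or OCP4 accounts for the Mup shift, since at least 93.6% of it was kept whichever was left out. Probes shared between near-identical Mup genes cannot be told apart from separate changes, since 0 of the probe sets reached the median level of all genes in their mean over the 14 arrays, and over all 10 the lowest correlation of 0.45 involves dim sets and excludes nothing, while 15 of 45 pairs exceeded 0.9; no biological explanation was tested.

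The counts of changed genes were set against other splits of the same arrays. For OCP1 minus OCP2 the 10 splits are too few for a share under 0.05, with 2388 genes for the real split and 0 for the highest other. For the other results only 1 split, the real one, gave as many genes. The other splits mix sorted groups, so the difference between groups enters the spread and lowers the count. They cannot exclude chance, since the real split was likely beforehand to rank first. Of 35 splits each, OCP4 minus OCP3 gave 6046 genes against 2 for the highest other, OCP3 minus OCP2 3502 against 692, OCP4 minus OCP1 5706 against 2656, OCP1 minus OCP3 5309 against 1846 and OCP4 minus OCP2 5251 against 2748. Of 100 splits each, the interaction gave 3915 against 2839 and the test over any of the 4 groups 8577 against 695.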
